A study of Mus musculus with 6 samples.

How the data were processed

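RNA was isolated with Trizol from liver metastases dissected under a microscope, per the labels' protocols, and the RNA went into a stranded mRNA library kit that selects polyadenylated RNA and marks strand with dUTP. FastQC 0.11.8, STAR 2.6.1, HTSeq and DESeq2 1.34.0 are named, without role or order, per the submitters' processing notes, and the genome build is GRCm39 (mm39). The strand setting of the counting is not given in the sources used here. The authors deposited a table of raw counts per gene for the 6 libraries, as whole numbers without normalization, with 24167 genes and a lowest row total of 2; 849 genes carry an identifier in place of a symbol, and 0 rows name no gene. The authors also deposited a DESeq2 table with log2 fold changes of shZdhhc17 against shSCR, p-values, q-values and a ranking score. Tested on each row, that score equals the log2 fold change times -log10 of the p-value, while the deposited column description gives the sign of the fold change times -log10 p. It lists 7509 q-values at 1. The deposited enrichment table holds normalized enrichment scores with p-values and q-values, made with fgsea per the file headers; the description of its columns names another contrast, while the table itself names this one. The gene sets were deposited as well, 3065 in all.

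The reference genome and annotation given with the data are of GRCm38, another build than the files use, so no coordinates are printed; symbols and identifiers are those of the count table, and 23174 of its identifiers are found in the table of gene names given with the reference. Of 739 genes on the fixed lists, 20 were not matched in the count table and are not analysed here. Groups were taken from the sample titles. All 6 columns of counts were matched to a sample.

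The main test was edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, two-sided) on the deposited counts, with TMM normalization and the filterByExpr filter, which left 15567 genes; the threshold was a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the log2 fold change and its F statistic. The common dispersion was 0.0552, a biological coefficient of variation of 0.235, on 4 residual degrees of freedom. CPM values use the TMM library sizes. Gene lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, for 39 of 42 fixed lists with at least 5 tested members and for deposited sets with at least 10. An estimated correlation, fry and the count of members adjusted over the list alone stand beside it. Levels of 19 cell type lists are means of log2(CPM + 1) per library, compared by an exact two-sided permutation test. R was version 4.3.3.

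Tested on simulated counts with the real means, library sizes and dispersions (shZdhhc17 minus shSCR, 200 changed genes among 15567), edgeR tested 15362 genes, recovered 39% of the genes changed 2-fold and 83% of those changed 4-fold, and called 9 unchanged genes. DESeq2 recovered 60% and 90% with 33 unchanged genes called, and voom 33% and 86% with 5. The simulated genes varied independently, without differences between libraries that many genes share. These shares therefore do not give the recovery in the real data. In 41 simulated lists of 20 independent genes, camera called the list shifted 2-fold and 0 of the others. Because those genes were independent, this does not show how often camera calls unchanged lists of correlated genes. In the real data the estimated correlation was, for example, 0.35 for neutrophil markers and 0.93 for the interferon gamma list. Total counts ran from 15832837 to 19186615. How far counting noise or the spread between libraries limits the precision of each named gene was not computed.

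The design, the lists and most of the other settings were fixed before the data were examined. The genes named are Zdhhc17; up to 10 genes in each direction with the largest fold change among those past the threshold with a mean of at least 1 CPM, groups that do not overlap and no predicted-gene or pseudogene symbol; for each list past camera, or with at least 2 members past the threshold, the 4 members with the smallest adjusted p; the most highly expressed member of each cell type list; and, since fewer than 10 passed in each direction, the 10 genes with the smallest p in each direction, as values that did not pass. Of the genes so chosen, 120 are reported, and a few others are not reported here.

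The settings fixed then were DESeq2 size factors, library totals alone, no filter on low counts, at least 10 counts in 3 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, the hepatocyte marker mean as a covariate, a 2-fold threshold, log2(CPM + 0.25) for marker levels, and leaving out each library. Added after seeing the data were the loss of Rn18s-rs5, edgeR without robust estimation, DESeq2 without each library, and fgsea 1.28.0 with 10000 initial permutations on both forms of the ranking score. Another 5 short gene lists, for primary granule genes, neutrophil receptors, early erythroid genes, globins and further mesothelial genes, were also chosen after seeing the results of the fixed lists, the further mesothelial genes before their own values were looked at.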

Results

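Liver metastases of 4T1 cells, a mouse triple-negative breast cancer line grown in BALB/c mice, were compared with and without silencing of Zdhhc17 in the injected cells. Zdhhc17 encodes a palmitoyltransferase, an enzyme that attaches the fatty acid palmitate to cysteines of other proteins. The series asks what loss of this enzyme does to metastases in a setting of neutrophil-mediated killing of cancer cells. Cells carrying a scrambled hairpin (shSCR) or a hairpin against Zdhhc17 (shZdhhc17) were injected hydrodynamically into the tail vein of female mice, 500000 cells per injection. Metastases were dissected from the livers on day 10, and polyadenylated RNA was sequenced in 3 libraries per group. The dissected tissue also holds liver and immune cells of the host, which carry no hairpin. The labels do not state outright that each library is a single animal, so p-values measure the spread between these samples. Gene counts summed to 19186615, 17847351 and 16129825 in shSCR replicates 1, 2 and 3, and to 15832837, 18234406 and 16051703 in shZdhhc17 replicates 1, 2 and 3. Each library detected between 21728 and 22269 genes.

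The libraries were not alike within either group. On the first principal component, which held 44.5% of the variance, shSCR replicate 3 lay at 65.4 and the other libraries between -33.2 and 12.3. On the second, which held 21.3%, shZdhhc17 replicate 1 lay at 46.8 and the other libraries between -22.4 and 5.68. The hepatocyte marker genes took 3.58% of all counts in shSCR replicate 3 and 6.79% to 8.93% in the others. In shSCR replicate 1, a copy of 18S ribosomal RNA, Rn18s-rs5, took 2.54% of the counts, against 0.194% to 0.412% elsewhere. The most alike pair of replicates, shZdhhc17 replicates 2 and 3, differed by a chi-square of 14.7 per gene over 15379 genes, where sampling noise gives about 1, so no library was counted as a repeat of another.

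The targeted transcript was lower in each silenced library. Zdhhc17 (ENSMUSG00000035798.15) stood at 33.7, 32.4 and 34.2 CPM (counts scaled to the normalized library size) in shSCR replicates 1, 2 and 3, a mean of 33.4 ± 0.902 (SD, n = 3). It stood at 25.9, 27.8 and 26.0 CPM in the shZdhhc17 replicates, a mean of 26.5 ± 1.07 (SD, n = 3). The groups did not overlap, which in an exact two-sided permutation test of 3 against 3 gives the smallest possible p, 0.1. The log2 fold change was -0.33 ± 0.11 (SE), with an adjusted p of 0.383 by edgeR's quasi-likelihood test, so it did not pass over all genes. The level is that of the whole tissue, host cells included. Among the 22 tested genes of the palmitoyltransferase list, which holds the Zdhhc family and its cofactors, 9 had a positive and 13 a negative log2 fold change, with a median of -0.072, and the list did not pass (camera adjusted p = 0.698). The 9 tested depalmitoylases, which remove palmitate, had a median of 0.15 (camera adjusted p = 0.461).

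**Figure D1:**
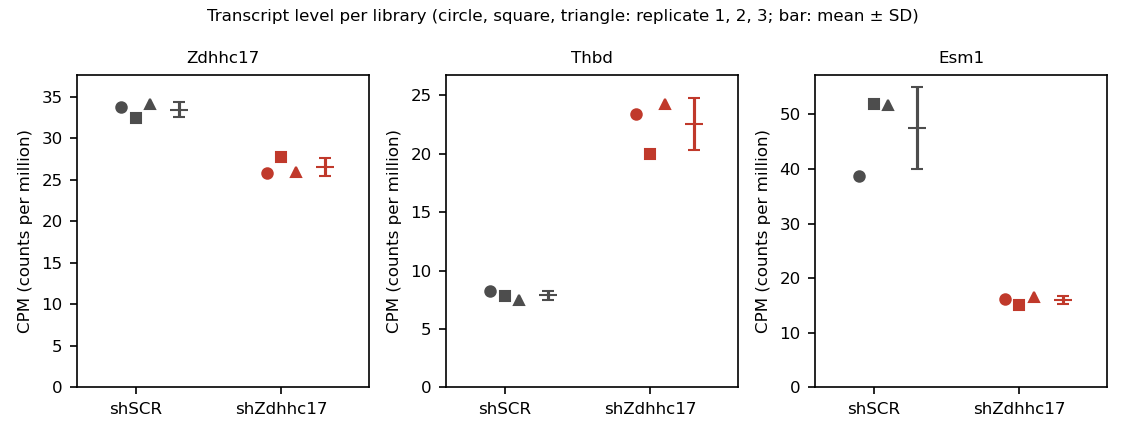
Transcript level in CPM (vertical axis, from 0) of Zdhhc17, Thbd and Esm1 in the 3 shSCR libraries (grey) and the 3 shZdhhc17 libraries (red); symbols mark the replicate number and bars the mean ± SD. Zdhhc17 lay between 25.9 and 27.8 in the silenced libraries and between 32.4 and 34.2 in the control libraries.

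Across the transcriptome no single gene passed the threshold, and the smallest p-values were those of Thbd and Esm1. Thbd, which encodes the thrombin receptor thrombomodulin, stood at 22.6 ± 2.25 CPM in shZdhhc17 and 7.87 ± 0.404 in shSCR metastases (SD, n = 3 each). Esm1, an endothelial proteoglycan gene, stood at 16.2, 15.2 and 16.6 CPM in shZdhhc17 replicates 1, 2 and 3, against 47.5 ± 7.52 in shSCR (SD, n = 3). Of 15567 genes tested with edgeR, 0 had an adjusted p under 0.05, and 1780 had an unadjusted p under 0.05 (735 with a higher and 1045 with a lower level in shZdhhc17), where chance gives 778. Other splits of the 6 libraries into 3 and 3 gave up to 2020 by the same test, and 2 of them, with 1878 and 2020, gave more than the real split. With library totals alone 397 were higher and 1544 lower, and without a single library the count ran from 950 (without shZdhhc17 replicate 3) to 2885 (without shSCR replicate 1). The smallest adjusted p was 0.0906. limma voom called 0 genes as well, with 1682 at an unadjusted p under 0.05. DESeq2 called 204, of which 98 were higher and 106 lower, the same number as in the authors' deposited table. Values of the groups did not overlap for 2661 genes, 17.1% of those tested, where chance gives 10% on average over splits. Genes that move together can carry the share of any split above or below that. The share in the other splits is not given, so the excess is not tied to the real groups. The DESeq2 count rested on single libraries: it was 24 without shZdhhc17 replicate 3, 88 without shZdhhc17 replicate 2, 101 without shSCR replicate 3, 115 without shSCR replicate 2, 371 without shZdhhc17 replicate 1 and 691 without shSCR replicate 1.

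**Figure D2:**
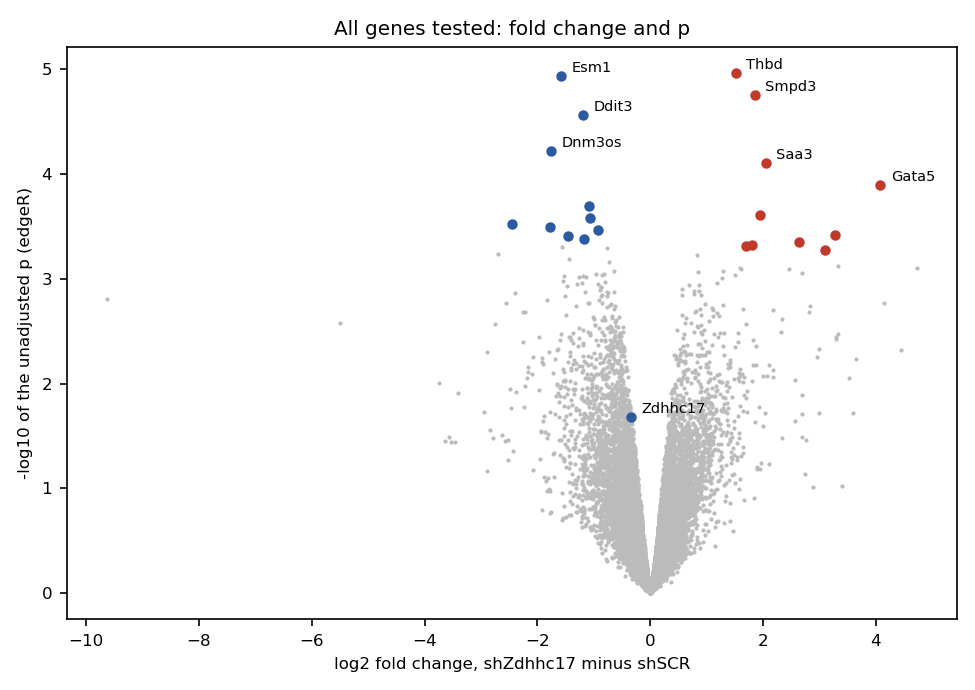
Log2 fold change of shZdhhc17 minus shSCR (horizontal axis) against -log10 of the unadjusted edgeR p (vertical axis) for the 15567 genes tested. Coloured points are Zdhhc17 and, in each direction, the 10 genes with the smallest p; none had an adjusted p under 0.05.

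The 10 genes with the smallest p on the higher side did not pass, and the groups did not overlap in any of them. Their log2 fold changes (± SE) were 1.52 ± 0.15 for Thbd (ENSMUSG00000074743.5; edgeR adjusted p = 0.0906) and 1.86 ± 0.19 for Smpd3 (ENSMUSG00000031906.10; edgeR adjusted p = 0.0920), a neutral sphingomyelinase that makes ceramide. Saa3, a serum amyloid gene of the acute phase response, had 2.05 ± 0.27 (edgeR adjusted p = 0.204), and the transcription factor gene Gata5 4.08 ± 0.57 (edgeR adjusted p = 0.282). The other members were Rdh9 of the retinol dehydrogenase family (1.94 ± 0.30), Lrrn4 (3.28 ± 0.54), Treh, which encodes trehalase (2.65 ± 0.45), the cell-surface proteoglycan gene Gpc3 (1.81 ± 0.31), Fyb2 (1.69 ± 0.29) and Stfa2, a stefin protease inhibitor gene (3.10 ± 0.54), each with an edgeR adjusted p of 0.307. Gata5, at 0.108 ± 0.0539 CPM in shSCR, and Treh, at 0.356 ± 0.235 CPM, rest on few counts. Stfa2 and Stfa3 have near-identical relatives, so how reads were shared among them is uncertain. In the authors' deposited table all 10 had a q under 0.05, such as 1.21e-10 for Thbd and 7.41e-11 for Smpd3.

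On the lower side, likewise without a gene that passed, Esm1 (ENSMUSG00000042379.9) had a log2 fold change of -1.57 ± 0.16 (SE; edgeR adjusted p = 0.0906). Ddit3 (ENSMUSG00000025408.16), the stress-induced transcription factor CHOP, had -1.19 ± 0.13 (edgeR adjusted p = 0.106), with 12.0 ± 0.345 CPM in shZdhhc17 and 27.5 ± 2.39 CPM in shSCR (SD, n = 3 each). Dnm3os, a noncoding transcript on the strand opposite Dnm3, had -1.76 ± 0.22 (edgeR adjusted p = 0.187); the strand setting of the counting is not stated, so reads of the gene pair cannot be told apart with certainty. The others, each with an edgeR adjusted p of 0.307, were Prss35 (-1.09 ± 0.16), the receptor phosphatase gene Ptpru (-1.07 ± 0.17), Gm20627 (-2.44 ± 0.39), Tmem95 (-1.78 ± 0.29), Trp53i11 (-0.93 ± 0.15), Acrbp (-1.46 ± 0.24) and the growth factor gene Fgf11 (-1.18 ± 0.20). In the authors' deposited table all 10 had a q under 0.05, the highest being 0.0118 for Gm20627.

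As groups, the neutrophil marker, granule, acute phase, fatty acid oxidation, hepatocyte, pericentral, mesothelial, platelet, erythroid, macrophage and proliferation lists rose relative to all other genes. The interferon, T cell, natural killer, dendritic, checkpoint, TNF, hypoxia, stellate, matrix and carcinoma lists fell. Of 39 fixed lists large enough to test, 22 passed limma's camera with its preset inter-gene correlation of 0.01, with 11 higher and 11 lower. No list held a member past the threshold over all genes. With a correlation estimated per list, 0 lists passed, the smallest adjusted p being 0.577. With fry, a self-contained test of whether a list's genes move on balance one way, 0 passed, the smallest adjusted p being 0.374, and 0 passed its mixed test, the smallest being 0.0605. Each list call therefore holds for the preset correlation only. Other splits of the 6 libraries into 3 and 3 gave 8 to 22 lists past camera, so the count does not single out the real groups.

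**Figure D3:**
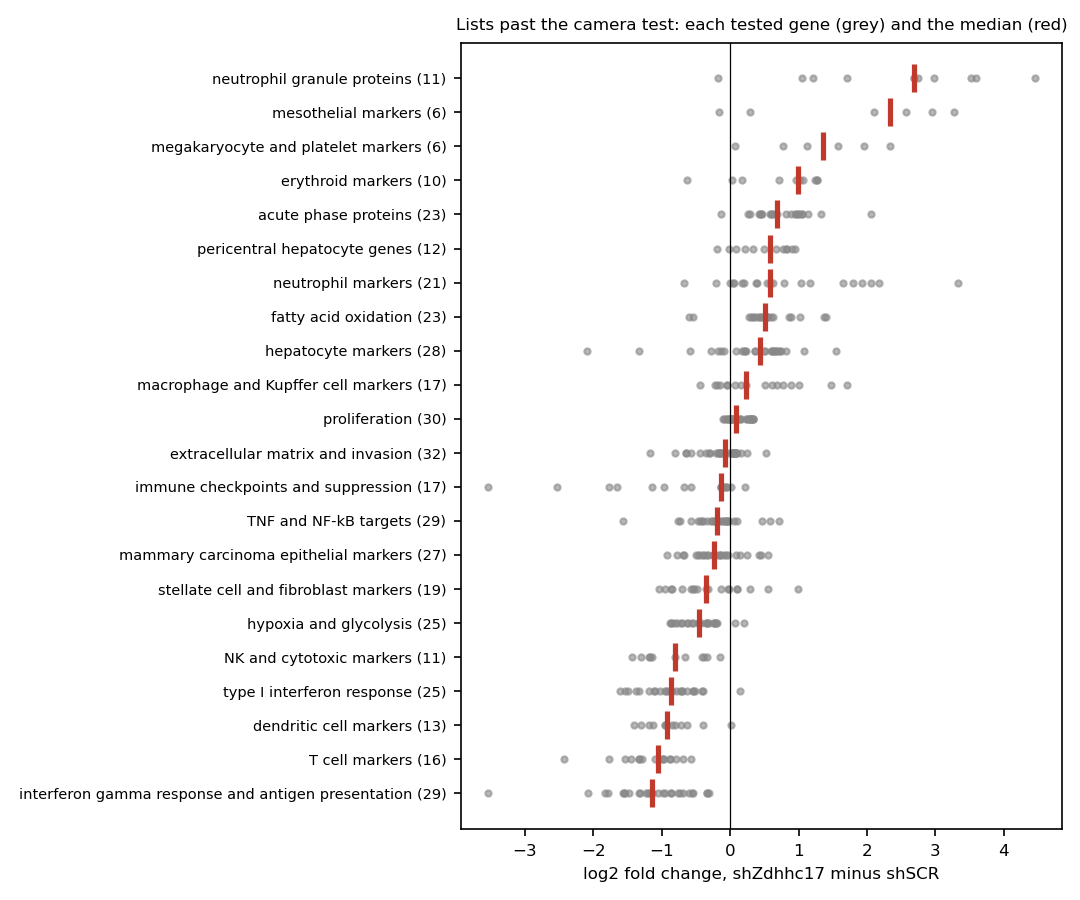
Log2 fold change of shZdhhc17 minus shSCR (horizontal axis) for each tested member (grey points) and the median (red mark) of the 22 lists past camera with the preset correlation, the number of tested members in brackets. The medians run from -1.14 for interferon gamma genes to 2.69 for neutrophil granule genes.

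Neutrophil marker and granule genes were higher in shZdhhc17 metastases, most of all those for granule contents. The granule list rose (median log2 fold change 2.69 over 11 genes, 10 of them positive; camera adjusted p = 4.58e-10, and adjusted p = 0.577 with an estimated correlation). Of its members, 9 were higher when adjusted over the list alone. They include Ctsg, Elane, Prtn3 and Mpo, the proteases and the peroxidase of primary granules, with log2 fold changes of 4.45 ± 1.12, 3.52 ± 1.00, 1.71 ± 0.51 and 3.59 ± 1.20 (SE); none passed over all genes. Mpo stood at 75.4 ± 66.8 CPM in shZdhhc17 and 6.22 ± 9.21 in shSCR (SD, n = 3 each). The marker list of neutrophils rose as well (median 0.58, 18 of 21 positive; camera adjusted p = 1.35e-07, and adjusted p = 0.682 with an estimated correlation). Adjusted over the list alone, 7 members were higher and 1, Slfn4, was lower (-0.68 ± 0.20; chosen after its value was seen). S100a9, the most highly expressed marker, stood at 244 ± 78.9 against 69.9 ± 48.7 CPM (log2 fold change 1.80 ± 0.52). S100a8, its partner in calprotectin, had 2.18 ± 0.62, the collagenase gene Mmp8 2.06 ± 0.58 and Stfa3 3.33 ± 0.61; none passed over all genes. The medians of the granule list without a single library ran from 2.10 to 4.87, the latter without shSCR replicate 2, where Ctsg, Elane and Mpo had 7.58, 5.37 and 6.36. Those sizes rest on few control counts. In shSCR replicates 1 and 3 Ctsg stood at 0 and 0.167 CPM, Elane at 0.545 and 0.391 and Mpo at 1.25 and 0.558. Mpo stood at 16.8 CPM in shSCR replicate 2 and 25.7 in shZdhhc17 replicate 2. Without shZdhhc17 replicate 3, Prtn3 had 0.99. Genes for neutrophil chemoattractants and growth factors (13 tested, median 0.0086; camera adjusted p = 0.892) and for the oxidative burst (9 tested, median 0.043, mean -0.19; camera adjusted p = 0.668) did not pass, the latter except without shSCR replicate 1 (median -0.16; camera adjusted p = 0.00949).

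Genes of hypoxia and glycolysis fell in shZdhhc17 metastases (median log2 fold change -0.46, 23 of 25 negative; camera adjusted p = 5.92e-11, and adjusted p = 0.577 with an estimated correlation). Adjusted over the list alone, 8 members were lower. P4ha1, a collagen prolyl hydroxylase gene, had -0.81 ± 0.15 (SE), the angiogenic growth factor gene Vegfa -0.85 ± 0.18, the carbonic anhydrase gene Car9 -0.87 ± 0.21 and the phosphofructokinase gene Pfkp -0.72 ± 0.19; none passed over all genes. Vegfa stood at 215 ± 29.9 against 389 ± 51.1 CPM (SD, n = 3 each). The mean level of the list was lower in each shZdhhc17 library (6.73 to 7.13 on the log2(CPM + 1) scale) than in each shSCR library (7.38 to 7.47). Its median ran from -0.56 to -0.34 without a single library.

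Stromal, matrix and carcinoma lists fell by less. Stellate cell and fibroblast markers had a median of -0.36 (14 of 19 negative; camera adjusted p = 0.0293, and adjusted p = 0.729 with an estimated correlation). The members differed in sign: Pdgfrb had -0.57 ± 0.15 and Fap -1.04 ± 0.29, while Reln had 0.99 ± 0.27 and Lrat, a vitamin A storage enzyme gene, 0.55 ± 0.21 (SE). Col3a1, the most highly expressed, had -0.49 ± 0.26. Matrix and invasion genes had a median of -0.081 (17 of 32 negative; camera adjusted p = 0.0415, and adjusted p = 0.696 with an estimated correlation). Adjusted over the list alone, 4 members were lower: the metalloproteinase genes Mmp12 (-0.81 ± 0.18) and Mmp13 (-1.17 ± 0.31), Tnc (-0.64 ± 0.16) and the lysyl oxidase gene Loxl2 (-0.64 ± 0.17). Mammary carcinoma epithelial markers had a median of -0.23 (21 of 27 negative; camera adjusted p = 0.0415, and adjusted p = 0.729 with an estimated correlation), with -0.51 ± 0.17 for Itgb4, -0.92 ± 0.34 for Krt19, -0.77 ± 0.34 for Epcam and 0.55 ± 0.22 for Cldn3. Targets of TNF and NF-kB had a median of -0.20 (24 of 29 negative; camera adjusted p = 0.0270, and adjusted p = 0.696 with an estimated correlation), with -0.73 ± 0.26 for Lif, -0.57 ± 0.20 for Traf1, -0.40 ± 0.15 for Il1b and -0.46 ± 0.18 for Tnfaip2. No gene named here passed over all genes. Without shSCR replicate 3 the stellate, matrix and TNF lists no longer passed (medians -0.11, -0.034 and -0.044; camera adjusted p = 0.413, 0.160 and 0.304), nor with the hepatocyte marker level as a covariate (medians -0.17, -0.028 and -0.11; camera adjusted p = 0.196, 0.112 and 0.11). Calls were also lost without other libraries: the stellate list did not pass without shZdhhc17 replicate 1 or 2 (medians -0.37 and -0.40, as large as with all libraries; camera adjusted p = 0.162 and 0.0810), the matrix list without shZdhhc17 replicate 3 (median -0.047; 0.301), the TNF list without shZdhhc17 replicate 1 (median -0.16; 0.125), and the carcinoma list without shSCR replicate 1, shZdhhc17 replicate 2 or shZdhhc17 replicate 3 (0.482, 0.120 and 0.301). The carcinoma median ran from -0.57 without shZdhhc17 replicate 1 to -0.082 without shZdhhc17 replicate 3.

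Interferon, T cell, natural killer and dendritic genes were lower in shZdhhc17 metastases, on a control group that was itself widely spread. The type I interferon list fell (median -0.87, 24 of 25 negative; camera adjusted p = 1.14e-09, and adjusted p = 0.696 with an estimated correlation), with -1.61 ± 0.48 for Oasl2, -0.91 ± 0.28 for Oasl1, -1.53 ± 0.50 for Oas2 and -1.09 ± 0.36 for Ifit3b (SE), all antiviral effector genes. The list of interferon gamma response and antigen presentation fell (median -1.14, 29 of 29 negative; camera adjusted p = 1.58e-06, and adjusted p = 0.696 with an estimated correlation). Ido1, a tryptophan-degrading enzyme gene, had -3.54 ± 1.38, and the class II histocompatibility genes H2-Aa, H2-Eb1 and H2-Ab1 had -1.48 ± 0.60, -1.54 ± 0.67 and -1.33 ± 0.60. H2-Aa stood at 174 ± 91.8 against 487 ± 292 CPM (SD, n = 3 each). T cell markers fell (median -1.05, 16 of 16 negative; camera adjusted p = 4.53e-05, and adjusted p = 0.696 with an estimated correlation), with -2.43 ± 1.00 for Cd8a and -1.33 ± 0.54, -1.45 ± 0.62 and -1.54 ± 0.67 for Cd3g, Cd3d and Cd3e. Natural killer and cytotoxic markers fell (median -0.81, 11 of 11 negative; camera adjusted p = 0.0311, and adjusted p = 0.729 with an estimated correlation), with -1.43 ± 0.53 for Ccl5, -1.19 ± 0.62 for Klrk1, -1.17 ± 0.74 for Gzmb and -1.30 ± 0.85 for Prf1. Dendritic cell markers fell (median -0.93, 12 of 13 negative; camera adjusted p = 1.70e-06, and adjusted p = 0.696 with an estimated correlation), and adjusted over the list alone 3 were lower: Itgax (-1.40 ± 0.38), Ccl22 (-1.31 ± 0.36) and Cd209a (-1.19 ± 0.31). Itgae had -0.81 ± 0.31. Immune checkpoint genes fell (median -0.13, mean -0.78, 15 of 17 negative; camera adjusted p = 0.0206, and adjusted p = 0.696 with an estimated correlation), with -1.66 ± 0.49 for Lag3, -0.67 ± 0.21 for the prostaglandin synthase gene Ptges and -2.53 ± 1.1 for Pdcd1lg2. No gene of these lists passed over all genes. Levels of these lists overlapped between the groups. Mean log2(CPM + 1) of natural killer markers was 1.01, 2.20 and 2.66 in shSCR replicates 1, 2 and 3. It was 1.06, 1.64 and 1.79 in shZdhhc17 (exact permutation p = 0.5). T cell markers stood at 0.940, 2.14 and 2.48 in shSCR and 0.803, 1.37 and 1.44 in shZdhhc17 (exact permutation p = 0.3). Estimated inter-gene correlations were 0.82 and 0.85, so a shared sign is not separate evidence per gene.

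The interferon gamma level was highest in shSCR replicate 3, at 8.21 on the log2(CPM + 1) scale, against 5.66 and 7.03 in shSCR replicates 1 and 2 and 5.33 to 6.70 in shZdhhc17. Without that library the list's median was -0.14 and it no longer passed (camera adjusted p = 0.153), and neither did the natural killer list (median -0.46; camera adjusted p = 0.683) or the checkpoint list (median -0.18; camera adjusted p = 0.335). Single genes moved as well: without shSCR replicate 3 the log2 fold changes were -1.38 for Ido1, -0.88 for Pdcd1lg2, -0.84 for Oasl2, -0.56 for Oasl1, -0.93 for Oas2, -0.64 for Klrk1 and -0.46 for Gzmb. Ido1 stood at 13.9 CPM and Pdcd1lg2 at 20.5 CPM in that library, and at no more than 2.30 and 4.71 CPM in any other. Without shSCR replicate 2, Cd8a, Cd3e and Prf1 had -1.45, -1.02 and -0.53. Without shSCR replicate 3 the medians of the type I interferon, T cell and dendritic lists were -0.32, -0.55 and -0.63, and these lists passed. The natural killer list also did not pass without shSCR replicate 2 or shZdhhc17 replicate 1 (medians -0.59 and -0.67; camera adjusted p = 0.132 and 0.330), and the checkpoint list without shZdhhc17 replicate 1 (median -0.24; 0.0809), a library without which the interferon gamma median was -0.72. With the hepatocyte marker level as a covariate, the natural killer and checkpoint lists did not pass (medians -0.38 and -0.12; camera adjusted p = 0.398 and 0.202). In leave-outs the natural killer median ran from -1.43 (without shZdhhc17 replicate 3) to -0.46, and the checkpoint median from -0.44 (without shSCR replicate 1) to -0.17 (without shZdhhc17 replicate 3). The interferon gamma, type I interferon, T cell and dendritic lists passed with that covariate, with medians of -0.20, -0.40, -0.54 and -0.61.

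**Figure D4:**
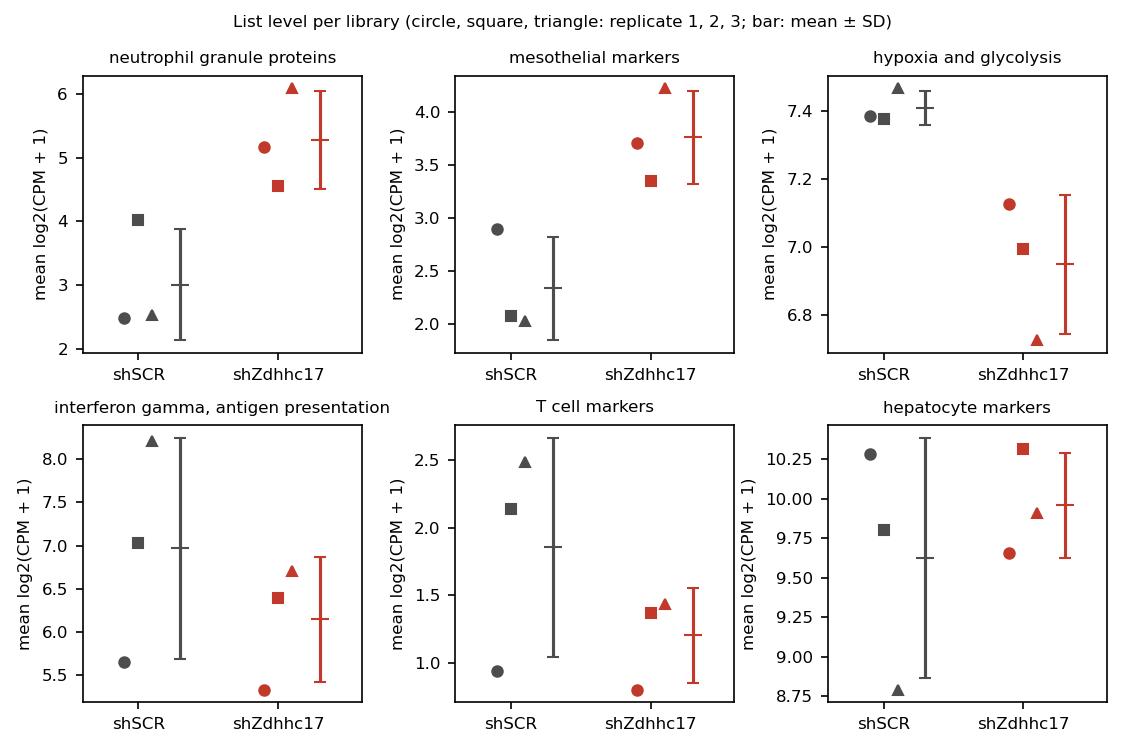
Mean log2(CPM + 1) over the tested members (vertical axes, each with its own range, not from 0) of 6 fixed lists in the shSCR (grey) and shZdhhc17 (red) libraries; symbols mark the replicate number and bars the mean ± SD, n = 3. The groups do not overlap for the granule, mesothelial and hypoxia lists, and shSCR replicate 3 has the highest interferon gamma level (8.21) and the lowest hepatocyte level (8.79).

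Acute phase, fatty acid oxidation, hepatocyte and pericentral genes were higher in shZdhhc17 metastases by median, but the levels per library overlapped. In each list shSCR replicate 1 lay above shZdhhc17 replicate 1. As mean log2(CPM + 1), acute phase proteins stood at 9.96 against 9.85 and fatty acid oxidation genes at 6.55 against 6.33. Hepatocyte markers stood at 10.3 against 9.65 and pericentral genes at 6.34 against 5.74. Acute phase proteins, which the liver secretes in inflammation, rose (median 0.69, 22 of 23 positive; camera adjusted p = 1.1e-11, and adjusted p = 0.682 with an estimated correlation). Adjusted over the list alone, 1 member, Saa3, was higher. The ferroxidase gene Cp stood at 3151 ± 439 against 1562 ± 304 CPM (SD, n = 3 each; log2 fold change 1.01 ± 0.26), and serum amyloid P, Apcs, had 1.33 ± 0.42 and the lipopolysaccharide-binding protein gene Lbp 1.06 ± 0.35 (SE). Fatty acid oxidation genes rose (median 0.51, 21 of 23 positive; camera adjusted p = 1.08e-07, and adjusted p = 0.696 with an estimated correlation), with 1.02 ± 0.28 for Cpt1a, the carnitine palmitoyltransferase of mitochondrial import, 0.63 ± 0.17 for Acaa1a, 0.59 ± 0.23 for Eci1 and 1.37 ± 0.54 for the nuclear receptor gene Ppara. Hepatocyte markers rose (median 0.43, 21 of 28 positive; camera adjusted p = 0.00494, and adjusted p = 0.729 with an estimated correlation), although the members with the smallest p differed in sign: Mup3 -2.10 ± 0.58, the glucose-6-phosphatase gene G6pc -1.33 ± 0.40, Mup20 1.54 ± 0.61 and Apoa1 0.62 ± 0.29. Mup genes are near-identical copies, and their separate counts are uncertain. Alb, the most highly expressed, stood at 20803 ± 4102 against 16109 ± 7759 CPM (log2 fold change 0.37 ± 0.46). Pericentral hepatocyte genes rose (median 0.58, 10 of 12 positive; camera adjusted p = 0.00499, and adjusted p = 0.696 with an estimated correlation), with 0.95 ± 0.35 for the glutamine synthetase gene Glul, 0.90 ± 0.39 for Gulo and 0.77 ± 0.44 for Slc1a2. None of these genes passed over all genes. Without shSCR replicate 3, the library with the lowest hepatocyte level, the hepatocyte median was 0.089 with camera's direction reversed (adjusted p = 0.889), the pericentral list no longer passed (median 0.36; camera adjusted p = 0.170), and the acute phase and fatty acid oxidation medians were 0.42 and 0.27, still past the threshold. The hepatocyte list also did not pass without shZdhhc17 replicate 2 (median 0.19; camera adjusted p = 0.137), nor the pericentral list without shZdhhc17 replicate 3 (median 0.35; 0.0655) or with the hepatocyte marker level as a covariate (median 0.34; 0.233). Without shSCR replicate 1 the hepatocyte, acute phase and fatty acid oxidation medians were 0.73, 1.04 and 0.82, while Mup3, at 902 CPM in that library and 173 to 395 in the other shSCR libraries, had -1.31, and G6pc -0.76. Mup20 had 0.90 without shZdhhc17 replicate 1, and Glul and Gulo 0.59 and 0.59 without shZdhhc17 replicate 3.

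Mesothelial, platelet and red cell genes were higher in shZdhhc17 metastases by median, but not all levels per library separated the groups. As mean log2(CPM + 1), erythroid markers stood at 4.73 in shSCR replicate 2 and 4.40 in shZdhhc17 replicate 1. Macrophage markers stood at 5.79 and 5.51 in the same libraries. Platelet markers did not overlap but came close, at 2.46 in shSCR replicate 2 and 2.48 in shZdhhc17 replicate 2. Mesothelial markers, genes of the lining of the liver surface and body cavities, rose (median 2.34, 5 of 6 positive; camera adjusted p = 2.90e-07, and adjusted p = 0.577 with an estimated correlation). Adjusted over the list alone, 4 were higher: Lrrn4 (3.28 ± 0.54), Upk1b (2.95 ± 0.76), Gpm6a (2.10 ± 0.56) and Upk3b (2.57 ± 0.74; SE). They were rare transcripts, Upk3b at 12.5 ± 5.39 against 2.10 ± 2.38 CPM (SD, n = 3 each), and Msln, the most highly expressed, had 0.28 ± 0.38. Megakaryocyte and platelet markers rose (median 1.35, 6 of 6 positive; camera adjusted p = 8.44e-05, and adjusted p = 0.682 with an estimated correlation), with 1.12 ± 0.32 for Pf4, 2.34 ± 0.89 for Ppbp, 0.77 ± 0.31 for Itga2b, 1.96 ± 0.88 for Gp1ba and 0.073 ± 0.19 for Itgb3. Erythroid markers rose (median 0.99, 9 of 10 positive; camera adjusted p = 0.00108, and adjusted p = 0.696 with an estimated correlation), with 1.25 ± 0.52 and 1.27 ± 0.54 for the globin genes Hbb-bt and Hbb-bs, whose near-identical sequences make their separate counts uncertain, 1.27 ± 0.59 for Alas2 and 1.02 ± 0.47 for Klf1. Macrophage and Kupffer cell markers rose (median 0.24, 11 of 17 positive; camera adjusted p = 0.00494, and adjusted p = 0.696 with an estimated correlation), with 0.61 ± 0.16 for Mrc1, 1.71 ± 0.53 for Marco, 1.48 ± 0.52 for Cd163, 1.01 ± 0.45 for Cd5l and -0.20 ± 0.19 for C1qa, the most highly expressed; without shSCR replicate 1 the list did not pass (median 0.061; camera adjusted p = 0.190). Proliferation genes rose slightly relative to the others (median 0.086, or -0.038 with library totals alone and 0.18 with the hepatocyte covariate; 24 of 30 positive; camera adjusted p = 0.0415, and adjusted p = 0.895 with an estimated correlation), with 0.34 ± 0.16, 0.34 ± 0.16 and 0.30 ± 0.16 for the replication helicase genes Mcm5, Mcm2 and Mcm4 and 0.30 ± 0.17 for Ccne2. The direction of the proliferation list turned without shSCR replicate 2 (median -0.030; camera adjusted p = 0.996) or shZdhhc17 replicate 1 (median -0.0062; camera adjusted p = 0.970). Medians of the macrophage list without a single library ran up to 0.59 (without shSCR replicate 2), those of the mesothelial list from 1.96 to 3.53 (without shSCR replicates 2 and 1) and those of the erythroid list from 0.66 to 1.90 (without shSCR replicates 1 and 2). Without shSCR replicate 2, Hbb-bt, Hbb-bs, Alas2 and Gp1ba had 2.16, 2.22, 2.24 and 3.48, Ppbp also lay over 1.5 times higher, and without shZdhhc17 replicate 3, Ppbp and Gp1ba had 1.46 and 1.04. Upk3b had 4.09 without shSCR replicate 1. No gene named here passed over all genes.

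The other 17 tested lists did not pass camera. Besides the 4 given above, these were death receptor and cell death genes (median -0.11, 20 of 28 negative; camera adjusted p = 0.415), monocyte markers (0.015; 0.432), B and plasma cell markers (0.37; 0.421), eosinophil, basophil and mast cell markers (0.075; 0.0849), periportal hepatocyte genes (-0.028; 0.913), cholangiocyte markers (0.045; 0.892), endothelial markers (0.11; 0.251), fatty acid and cholesterol synthesis (0.10; 0.224), xenobiotic and bile acid metabolism (0.089; 0.247), the unfolded protein and integrated stress response (0.0085; 0.668), dissociation and immediate early genes (-0.11; 0.0802), mitochondrially encoded genes (-0.086; 0.602) and cytosolic ribosomal proteins (0.062; 0.390), each as median log2 fold change and camera adjusted p. When adjusted over the list alone, 4 of their members passed, chosen after their values were seen except Ddit3: Prg2, an eosinophil granule gene (4.15 ± 0.86, SE), Hsd17b13 (0.83 ± 0.19), Ddit3 and Atf3 (-0.74 ± 0.17). The camera direction was opposite in sign to the median for chemoattractants, the oxidative burst, periportal genes and the unfolded protein response, whose medians were near 0. Leaving out a library brought several past the threshold, most often the eosinophil list (camera adjusted p = 0.00691, 5.36e-04 and 0.0207 without shSCR replicate 2, shSCR replicate 3 and shZdhhc17 replicate 1) and xenobiotic metabolism (0.0259, 0.0437 and 0.0178 without shSCR replicate 1, shSCR replicate 2 and shZdhhc17 replicate 1). The others were B cell markers (0.0208 and 0.00609 without shSCR replicate 2 and shZdhhc17 replicate 1), fatty acid synthesis (0.0184 and 0.00438 without shSCR replicate 3 and shZdhhc17 replicate 1), ribosomal proteins (0.0120 and 0.00910 without shSCR replicate 3 and shZdhhc17 replicate 2), immediate early genes (0.0267 without shSCR replicate 2) and mitochondrial genes (0.0217 without shSCR replicate 3). With the hepatocyte marker level as a covariate, the periportal list passed in the lower direction (median -0.16; camera adjusted p = 0.0209), and ribosomal proteins (0.15; 0.0156) and the eosinophil list (0.31; 0.0448) in the higher. Pancreatic acinar (1 gene tested), skeletal muscle (2) and adipocyte (3) markers were too few for a test, with median log2 fold changes of 0.13, -0.42 and 0.33. In the adipocyte list Cidec (2.82 ± 0.61; chosen after its value was seen) and Fabp4 (-0.55 ± 0.16) passed when adjusted over the list alone.

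As levels per library, 3 of the 19 cell type lists separated the groups, where chance gives 1.9: neutrophil markers (4.23 ± 0.194 against 3.50 ± 0.360), mesothelial markers (3.76 ± 0.439 against 2.34 ± 0.488) and megakaryocyte and platelet markers (2.88 ± 0.422 against 2.08 ± 0.332), as mean log2(CPM + 1) ± SD with n = 3 in shZdhhc17 and shSCR. Each had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, so none could pass, and 0.475 after adjustment over the 19 lists. Of the most highly expressed marker of the other types, Fn1 (0.52 ± 0.30, monocyte list), Fscn1 (0.017 ± 0.23, dendritic list), Lck (-0.99 ± 0.49, T cells), Ighm (0.37 ± 0.34, B cells), Kit (-0.26 ± 0.24, mast cell list), Spp1 (-0.20 ± 0.31, cholangiocytes), Eng (-0.028 ± 0.20, endothelium), Cela1 (0.13 ± 0.25, pancreas) and Tnnt3 (-0.93 ± 0.45, muscle) did not pass over all genes (log2 fold change ± SE).

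Among the gene sets that the submitters deposited, clotting, complement and fatty acid sets rose and interferon sets fell. Of 2430 sets with at least 10 tested members, 146 passed camera with the preset correlation, 109 higher and 37 lower, and 0 passed with an estimated correlation or with fry. The fibrin clot cascade led the higher sets (34 genes, median log2 fold change 0.59; camera adjusted p = 1.04e-09, and adjusted p = 1.00 with an estimated correlation). The KEGG set of complement and coagulation followed (65 genes, median 0.55; camera adjusted p = 8.89e-09, and adjusted p = 1.00 with an estimated correlation), and the Hallmark set of fatty acid metabolism had a median of 0.22 over 144 genes (camera adjusted p = 1.98e-05, and adjusted p = 1.00 with an estimated correlation). Interferon gamma signalling of Reactome led the lower sets (89 genes, median -0.41; camera adjusted p = 7.37e-05, and adjusted p = 1.00 with an estimated correlation), and the Hallmark interferon alpha response had a median of -0.35 over 102 genes (camera adjusted p = 7.91e-05, and adjusted p = 1.00 with an estimated correlation). Without shSCR replicate 3 the count of sets was 42, without shSCR replicate 1 it was 317, and with the hepatocyte marker level as a covariate 71. Which of the sets named here passed in those settings is not given. Their calls were therefore not separated from the hepatocyte share of the libraries, which was lowest in shSCR replicate 3, at 3.58% of counts. Other splits of the 6 libraries into 3 and 3 gave 13 to 555 sets. In the authors' deposited table of enrichment, 18 of 3059 sets had a q under 0.05, 12 higher and 6 lower. Hallmark coagulation led them with a normalized enrichment score of 2.09 (q = 1.18e-05), and neutrophil degranulation had 2.04 (q = 2.69e-10) and interferon gamma signalling -1.86 (q = 0.0278) in the authors' deposited table. Of those 18 sets, 13 passed camera in the same direction, neutrophil degranulation with a camera adjusted p of 0.0311 (adjusted p = 1.00 with an estimated correlation).

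The calls of the authors' deposited table and those of edgeR were set side by side. The authors' deposited table listed 204 genes with a q under 0.05, and edgeR shared 0 of these at the same threshold. Of the 198 that passed the edgeR count filter, all 198 had the same sign and an unadjusted edgeR p under 0.05, and 196 had groups that did not overlap. DESeq2 run on the deposited counts gave log2 fold changes within 5.00e-07 of those in the authors' deposited table and called the same 204 genes.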

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

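Tests chosen only after the results were seen are the loss of Rn18s-rs5, edgeR without robust estimation, DESeq2 without each library, and the other ranking score. Zdhhc17 had a negative log2 fold change under every alternative run, from -0.47 (library totals alone) to -0.31 (without shZdhhc17 replicate 1), and passed in none. Library totals alone moved the median log2 fold change of all genes to -0.13.

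The count of 0 genes by edgeR became 3 without a filter on low counts (2 higher, Smpd3 and Thbd, and 1 lower, Esm1). It became 1 lower gene with the hepatocyte covariate (Mup9, log2 fold change -4.00) and 1 lower gene without shSCR replicate 3 (Scgb1a1), both chosen after their values were seen; leaving out each library gave 0 to 1 genes, 0 higher and 0 to 1 lower. DESeq2 gave 204 genes, 98 higher and 106 lower, and 24 to 691 when a library was left out. The cause of these differences was not tested. Calls shared with the deposited table were 0 with edgeR, 204 with DESeq2 and 3 without the filter.

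Of the fixed lists 22 passed, and 0 with an estimated correlation and 0 with fry; 18 to 24 passed without a library, and 11 of the 22 passed in each leave-out. Of the deposited sets 146 passed, 71 with the hepatocyte covariate, 0 with an estimated correlation, 0 with fry, and 42 to 317 without a library. Cell type lists that separated the groups were 3, or 5 with a pseudocount of 0.25, and 4 to 8 without a library, where smaller groups overlap less often by construction. fgsea on the deposited score called 18 sets, 15 of them among the 18 deposited calls; on the score that the column description states it called 221, 17 of them among those deposited.

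With the replicate number as a block, edgeR called 0 genes, camera 23 lists (the eosinophil list added) and 170 sets, and Zdhhc17 had -0.33. The deviations of same-numbered libraries correlated at -0.03, 0.25 and -0.03. Both libraries of replicate 2 correlated best with each other, and the others did not correlate best with their own number. The labels state no pairing beyond the number, and with 3 libraries per group these correlations cannot show whether a day or batch was shared.

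Among 120 named genes, 5, none of them called, changed sign, and in 49 the log2 fold change moved by over 1.5 times without a single library. In leave-outs Fscn1 ran from -0.20 to 0.13, Eng from -0.18 to 0.11, Msln from -0.095 to 0.69, Itgb3 from -0.079 to 0.28 and Cela1 from -0.0047 to 0.35. With library totals Fscn1 had -0.12 and Itgb3 -0.072, and with the hepatocyte covariate Eng had 0.0055. In leave-outs the hepatocyte list's median ran from 0.089 (with camera's direction down) to 0.73 and the proliferation list's from -0.030 to 0.22, and with library totals the latter was -0.038. The cause was not tested.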

Other observations

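The tests in this part were chosen after the results were seen, except the 10 splits of the libraries. The further mesothelial genes were picked after the result of the mesothelial list and before their own values were looked at.

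Some transcripts of lung epithelium, chosen after their values were seen, differed widely between libraries. Scgb1a1, the secretoglobin of airway club cells, stood at 19.3, 46.8 and 0.781 CPM in shSCR replicates 1, 2 and 3 and at 0, 0 and 0.0659 in shZdhhc17. The surfactant genes Sftpc, Sftpb and Sftpa1 stood at 60.4, 17.0 and 15.8 CPM in shZdhhc17 replicate 2, and at no more than 4.74, 1.05 and 1.00 CPM in any other library. Ms4a3, a gene of granulocyte and monocyte progenitors, stood at 6.16, 3.11 and 18.3 CPM in shZdhhc17 and at no more than 0.680 in shSCR (log2 fold change 4.72 ± 0.86, edgeR adjusted p = 0.307). The 4 globin genes had a median log2 fold change of 1.15.

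The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split is among the 10, and the shares below count it. edgeR called 0 genes in all 10, and the highest of the other splits gave 0; at an unadjusted p under 0.05 the real split gave 1780 and the highest other 2020. DESeq2 called 204 genes in the real split and as many or more in 2 of 10, the highest other split, shSCR replicate 1 with shZdhhc17 replicates 2 and 3 against the rest, giving 306. Of the fixed lists 22 passed, as many in 2 of 10 splits, and the other splits gave 8 to 22. Of the deposited sets 146 passed, as many or more in 7 of 10. The highest other, 555, came from shSCR replicate 1 with shZdhhc17 replicates 1 and 3 against the rest, several times the real count. The counts of lists and of sets therefore do not single out the real groups. The cause was not tested. Samples that differ in ways the groups do not follow and the preset correlation both stay open. With an estimated correlation, 0 lists and 0 sets passed.

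Neutrophil granule genes were higher in shZdhhc17. A single library as the source is argued against, since the median log2 fold change of the list stayed at 2.10 or above in each leave-out, against 2.69 with all libraries. More mature neutrophils stay open: the median of the granule list lay above that of the neutrophil marker list by 2.12, but markers such as Stfa3 (3.33), S100a8 (2.18) and Mmp8 (2.06) had log2 fold changes near that of the granule list. Blood-forming cells in the tissue stay open and cannot be told apart from an effect of the silencing, since the values point both ways. The megakaryocyte list had a median of 1.35, with 6 of 6 positive, and Ms4a3 had 4.72. The 5 early erythroid genes had a median of 0.18, 4 of them positive, with shZdhhc17 replicate 1 below the shSCR mean. Of these, Klf1 had 1.02 ± 0.47 (SE), at 0.807 against 0.393 CPM without overlap of the groups, while Car1 had -0.63 ± 0.62. Tfrc, the most abundant of the 5, stood at 73.8 against 72.8 CPM. That level would hide a small share, so Tfrc does not decide. The 4 primary granule genes had a median of 3.56 and 6 receptor genes 0.56, sets chosen after the values were seen, which exclude nothing. Of the receptor genes 5 were positive, while the most abundant, Csf3r, stood at 46.3 ± 7.15 CPM in shZdhhc17 and 46.5 ± 14.2 in shSCR (SD, n = 3 each).

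Mesothelial genes were higher in shZdhhc17. A single library as the source is argued against, with a median of 1.96 or above in each leave-out, against 2.34 with all libraries. Liver surface tissue in the dissected pieces may be a source and cannot be told apart from an effect of the silencing: 8 further mesothelial genes had a median of 0.38, 6 of them above 0. Muc16 had 3.33 ± 0.78 and Aldh1a2 -0.59 ± 0.14, and abundant members such as Rarres2, at 464 CPM in shSCR, would hide a small share.

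Interferon and antigen presentation genes were lower in shZdhhc17. For the interferon gamma list the values go with a pattern carried by shSCR replicate 3, without which its median was -0.14. The type I interferon list still passed camera with the preset correlation without that library. Its median was then -0.32, against -0.87 with all libraries, so part of its fall remained. The values also go with a difference in T cells. Over the 6 libraries the T cell and interferon gamma levels had a Pearson r of 0.966 (exact permutation p = 0.00139, the smallest possible). Their Spearman rho was 1.00 (exact permutation p = 0.00278), and r was 0.993 without the 2 libraries farthest from the median. This was the only relation computed, and none was computed for the natural killer list. Type I interferon levels put the 6 libraries in the same order as the T cell list. They were 4.54, 5.20 and 6.05 in shSCR replicates 1, 2 and 3, and 4.09, 4.66 and 4.84 in shZdhhc17. The order of the libraries is therefore not particular to T cells, and the relation does not single them out. Neither test says whether the cells or the interferon came first, and an effect of the silencing stays open.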
